A study of Sordaria fimicola with 6 samples.

How the data were processed

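RNA was measured in vegetative mycelium of Sordaria fimicola, a homothallic ascomycete (a fungus that can complete its sexual cycle without a partner), by sequencing 6 libraries on an Illumina NextSeq 500. Cultures of the wild type and of the mutant Sfwc-1(∆lov) had been kept in darkness for 2 days. They were frozen without light, or after 15 or 45 min of blue light, and each of the 6 combinations of strain and light has 1 library. The labels do not say whether the libraries came from separately grown cultures.

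According to the submitters' notes, the authors aligned the reads with Bowtie to a de novo transcriptome assembly and quantified them with RSEM, and also used edgeR; no versions are given. The authors deposited expected counts (RSEM estimated counts, not normalised) for 53339 assembled features. They also deposited FPKM values scaled across libraries by TMM factors, used here only as an alternative. The authors gave each feature the identifier (ID) of a Neurospora crassa gene, except for 26 features, and the criteria of this matching are not stated. The 26 features held at most 0.000578% of a library's counts and were left out.

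Expected counts were summed over the features of an ID, which gave 9134 IDs with a median of 5 features among those kept. The largest number of features under one ID was 253, for bli-3 (NCU07267), and a median of 94.4% of a kept ID's counts lay on its top feature. Because features of related genes or of unrelated fragments can carry the same ID, a sum is called a gene here but may hold more than 1 gene of Sordaria. Sums were rounded to whole counts for the intervals. IDs with a mean of at least 20 expected counts over the 6 libraries were kept, 7810 in all, with 99.9% of the counts.

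Libraries were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3. Levels are in CPM, counts scaled to a common library size with these factors, and log2 folds used a prior count of 2. Genes were called higher or lower between single libraries when the ratio was at least 2-fold and its exact 95% Clopper-Pearson interval excluded 1. This is a rule of size: it involves no replicates and gives no p-value. Intervals cover counting error only, and so does the floor of 3 counts per library used where a count was 0. There were 7 such comparisons: each light time against darkness within a strain, and mutant against wild type in each condition.

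With no replicates, the light and interaction tests treated the 15 and 45 min libraries of a strain as 2 lit libraries, so that their error is the spread between different light times. The strain test took the light condition as a block, so that its error is the variation of the strain difference between the 3 conditions. edgeR's quasi-likelihood test was run for 4 comparisons with 2 residual degrees of freedom and a Benjamini-Hochberg threshold of 0.05 over the 7810 genes. They were light against dark in each strain, the difference of these light responses between the strains (the interaction), and mutant against wild type with the light condition as a block. In the light and interaction tests a lone dark library was assumed to vary like the lit ones. Standard errors (SE) are those of the fitted log2 folds.

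Before the data were examined, 9 lists with 76 Neurospora genes were fixed: photoreceptors, clock genes and photolyase; carotenoid synthesis; light-responsive transcription factors; conidiation and clock-controlled genes; mating and fruiting body; melanin synthesis; oxidative stress enzymes; heat shock proteins; and housekeeping genes. Gene names come from general knowledge of Neurospora and not from the deposited tables, and 68 members passed the count minimum. List medians were set against 10000 random lists of as many genes matched for expression in 10 bins. Adjusted p-values were computed over all genes and over each list alone. The naming rule, fixed at the same time, was to name Sfwc-1, list members, and at most 2 higher and 2 lower further IDs per comparison, from the 10 most changed with a mean of at least 50 counts or the 10 with the smallest adjusted p.

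The pipeline was tested on simulated data with 67 or 66 genes changed at each size. The wild-type light test recovered 13.4% of genes changed 2-fold, 70.1% at 4-fold and 97.0% at 8-fold, with 6 unchanged genes called. The interaction test recovered 4.48%, 25.4% and 74.2%, the mutant light test 11.9%, 68.7% and 95.5%, and the strain test 38.8%, 97.0% and 100%. The rule of size recovered 56.7%, 95.5% and 100%, but also called 616 unchanged genes. Each simulated gene had the spread fitted for its expression level and the same change in each affected library. Genes that vary more, or whose change differs between light times, are not covered by these percentages. In the real data per-1 (NCU03584), at -4.02 (log2), had an adjusted p of 0.108 over all genes in the edgeR strain test. Unchanged pairs of libraries were further simulated 100 times for each comparison, with the spread estimated from all libraries, and for the light comparisons also with the spread of the strain's own lit pair. With no replicates, the spread from all libraries also rests on the lit pairs, and so includes any change between light times.

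Alternatives were total-count scaling, DESeq2 1.42.0 size factors, no count minimum or one of 100, prior counts of 0.5 and 10, the top feature per gene, features not summed, the authors' FPKM with pseudocounts of 1 and 0.1, removal of the 10 most abundant genes, the DESeq2 Wald test, limma-voom (limma 3.58.1), and a strain test with no light block. FPKM values were summed over the features of an ID, and a ratio of at least 2-fold alone made a call, without the interval. Fits without 1 library or pair, and removal of 24 features of the assembly components with the 4 most abundant features, were chosen after the data were seen. Without a lit library the light and interaction tests have 1 residual degree of freedom, and their spread is that of the other strain's lit pair alone. The strain test without any 1 library or pair also has 1 residual degree of freedom, since the light block fits a library without its partner exactly.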

Results

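Transcript counts were obtained for 2 strains of Sordaria fimicola in darkness and after blue light, with 1 library in each of the 6 groups and no replicates. Total expected counts were 7682783 for the wild type in the dark, 11191088 at 15 min and 8156707 at 45 min. For the mutant they were 10171566 in the dark, 6254720 at 15 min and 6746962 at 45 min. A small set of abundant RNAs took unequal shares: the 10 most abundant genes held 19.6%, 27.2% and 18.4% of wild-type counts (dark, 15 and 45 min) and 12.8%, 46.1% and 27.5% of mutant counts. Across genes, log2 levels correlated between libraries with Pearson's r from 0.857 to 0.967, where genes are not independent replicates. Fitted variation between libraries beyond counting error (biological coefficient of variation) was 26.8% over the 6 libraries, 30.8% between the lit wild-type libraries and 22.2% between the lit mutant libraries. Counts of genes by size that follow cover between-library spread only through simulated unchanged pairs, whose mean counts stand beside them. The spread of these pairs is that between light times within a strain, so a true change between those times would raise the simulated counts.

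The mutated gene, Sfwc-1, corresponds to NCU02356 (wc-1), which encodes the blue-light receptor of the White Collar complex in Neurospora. Its summed counts were 892, 6758 and 3176 in the wild type (dark, 15 and 45 min) and 752, 149 and 289 in the mutant. Scaled, these were 100 CPM in the dark, 672 CPM at 15 min and 376 CPM at 45 min in the wild type, against 58.9, 32.5 and 42.7 CPM in the mutant. Of the 12 features with this ID, 1 had 48.4, 75.7 and 11.7 expected counts in the wild type and 0 in each mutant library. Another had 36, 10 and 11.7 expected counts in the mutant and 0 in each wild-type library. Which part of the gene these features cover is not known from the tables.

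The first comparison asks which genes responded to blue light in the wild type. Carotenoid synthesis genes had some of the largest differences: al-1 (NCU00552, phytoene desaturase) was 1657-fold higher at 15 min (95% interval 1244 to 2253) and 1490-fold higher at 45 min (1119 to 2026). The other carotenoid genes al-2 (NCU00585) and al-3 (NCU01427) were 198- and 61.0-fold higher at 15 min, and 117- and 38.6-fold higher at 45 min. Of the 5 members, 4 were higher at both times, with list medians of 5.92 and 5.27 (log2). Among photoreceptor, clock and photolyase genes, 8 of 9 were higher at 15 min and 7 of 9 at 45 min, with medians of 2.74 and 2.51. Both lists lay above each of 10000 matched random lists at both times.

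Within that photoreceptor list, vvd (NCU03967), a small blue-light receptor active in light adaptation, was 572-fold higher at 15 min (352 to 1001) and 2570-fold higher at 45 min (1583 to 4497), from 16 counts in the dark. The cryptochrome gene cry (NCU00582) was 331- and 380-fold higher. Smaller ratios were found for the clock gene frq (NCU02265; 9.70 and 6.10), the photolyase gene phr (NCU08626; 7.44 and 9.15) and frh (NCU03363; 4.30 and 5.72). The receptor genes wc-1 and wc-2 (NCU00902) had ratios of 6.71 and 2.79 at 15 min, and 3.75 and 2.89 at 45 min. The opsin gene nop-1 (NCU10055) was 2.96-fold higher at 15 min.

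**Figure D1:**
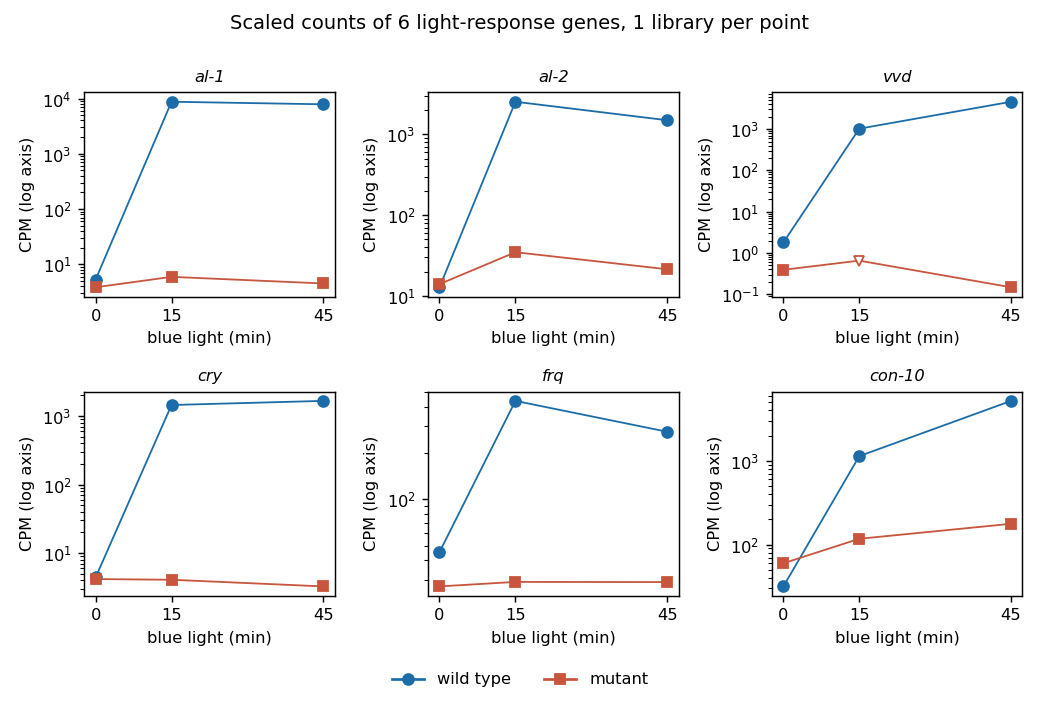
CPM (scaled counts, log axis) of 6 light-associated genes against minutes of blue light, wild type as blue circles and mutant as red squares, 1 library per point. al-1 goes from 5.27 to 8738 and 7859 in the wild type and lies between 3.83 and 5.92 in the mutant; the open triangle is vvd in the mutant at 15 min, with 0 counts, drawn at the floor of 3 counts.

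Conidiation and clock-controlled genes were also higher in lit wild-type mycelium, 8 of 11 at 15 min and 7 of 11 at 45 min, with medians of 2.49 and 3.26 (7 at 15 min with total-count scaling or in the authors' FPKM). Examples are con-10 (NCU07325; 36.0-fold at 15 min and 164-fold at 45 min), bli-3 (NCU07267; 11.7 and 21.2, a sum of 253 features; log2 folds of 3.54 and 4.38 from its top feature), bli-4 (NCU08699; 12.1 and 11.1) and con-6 (NCU08769; 10.1 and 9.63). Light-responsive transcription factors went both ways at 15 min, with 4 of 7 higher and 2 lower, and 5 of 7 were higher at 45 min; with total-count scaling 2 were higher at 15 min and 4 at 45 min. The repressor gene csp-1 (NCU02713) was 31.7-fold higher at 15 min and 7.99-fold at 45 min, while the conidiation regulator fl (NCU08726) had ratios of 4.47 and 9.80. adv-1 (NCU07392) and vad-3 (NCU06407) were 2.42- and 2.13-fold lower at 15 min, the latter -0.15 (log2) in the authors' FPKM.

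Genes of melanin synthesis were lower in lit wild-type mycelium, all 4 of 4 at both times, with medians of -2.69 and -2.76. The polyketide synthase gene per-1 (NCU03584) was 6.45-fold lower at 15 min and 4.27-fold lower at 45 min, and tetrahydroxynaphthalene reductase-1 (NCU06905) was 6.60- and 12.0-fold lower. In the authors' FPKM, per-1 at 15 min was below the 2-fold limit (-0.40, log2). Oxidative stress enzymes went both ways: the catalase gene cat-1 (NCU08791) was 14.2- and 8.43-fold higher and cat-3 (NCU00355) 3.13- and 6.02-fold lower. Of 11 mating and fruiting body genes, mat A-1 (NCU01958), a mating-type regulator, was 2.04- and 3.05-fold lower, and the other 10 passed the size rule at neither time (pre-2 and lae-1 were -1.10 and -1.19 at 15 min with total-count scaling); its 15 min value fell short of 2-fold with DESeq2 size factors (-0.99). Heat shock and housekeeping genes had no member past the rule at 15 min (grp-78 was -1.03, log2, with total-count scaling, and hsp98 1.02 with DESeq2 size factors and 1.03 in the authors' FPKM) and 1 each, lower, at 45 min: grp-78 (2.04-fold; -0.88, log2, in the authors' FPKM) and the enolase gene eno (2.82-fold), while hsp98 was 1.05 in FPKM.

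Over all genes, 775 were higher and 426 lower at 15 min, and 768 higher and 808 lower at 45 min. Simulated unchanged pairs gave 313 and 304 at 15 min and 311 and 315 at 45 min, or 475 and 471, and 481 and 479, with the spread of the wild-type lit pair, so the lower count at 15 min did not exceed the latter. Beyond 16-fold, 52 genes were higher at each time, and 5 and 17 were lower. NCU16961 had 83 counts at 15 min against 8540 in the dark, and NCU08533 had 13995 at 45 min against 16. The genes higher at both times numbered 500, against 76.2 for independent sets, 95.3 with the spread of all libraries and 165 with that of the wild-type lit pair. For lower genes the numbers were 281, 44.1, 50.3 and 95.3, and both times share 1 dark library. Higher genes made up 64.5% of the calls at 15 min and 48.7% at 45 min, but 36.4% and 37.8% with total-count scaling, which moved the median of all genes to -0.43 and -0.16 (log2), and 67.7% and 64.7% in the authors' FPKM.

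In the edgeR test of light against dark in the wild type, 140 genes rose and 57 fell. The smallest adjusted p, 0.00597, was shared by al-1 (log2 fold 10.61, SE 0.635), cry (8.47, SE 0.525) and NCU00999 (7.18, SE 0.473), each higher in 2 of 2 lit libraries. NCU04058 fell by 4.79 (SE 0.386, adjusted p = 0.0135). Adjusted over the list alone, 4 of 5 carotenoid genes changed (4 over all genes tested), 7 of 9 photoreceptor, clock and photolyase genes (5), 6 of 7 transcription factors (0), 7 of 11 conidiation genes (5), 4 of 4 melanin genes (3) and 3 of 7 oxidative stress enzymes (1). In edgeR 0 mating, 0 heat shock and 0 housekeeping genes passed either way (1, 2 and 0 unadjusted), and the DESeq2 Wald test and limma-voom also called 0 over these lists alone, but 1 mating gene passed with total-count scaling or no count minimum and 1 housekeeping gene without the wild-type 15 min library. The transcription factors fl, csp-1 and adv-1 had log2 folds of 2.84, 4.31 and -0.98, with adjusted p over the list alone of 0.0162, 0.0162 and 0.0353. Without the mutant 15 min or the mutant 45 min library, 0 genes passed over all genes (922 and 920 unadjusted), but over the lists alone 4 carotenoid, 7 photoreceptor, 4 melanin, 6 conidiation and 4 transcription factor genes passed. Without the wild-type 15 or 45 min library, 368 and 355 genes rose, and 262 and 109 fell. Each of these 4 fits has 1 residual degree of freedom and takes its spread from the lit pair of 1 strain alone.

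The same question was asked of the mutant. Carotenoid genes showed little of the wild-type difference: al-1 had 3.83 CPM in the dark, 5.92 at 15 min and 4.50 at 45 min, although it passed 2-fold in the authors' FPKM (1.33 and 1.03, log2). The list medians were 0.50 and 0.22, which became -0.27 and -0.09 with total-count scaling. Of the photoreceptor list, 1 of 9 was higher at each time, nop-1 (3.18- and 3.23-fold; 0.90, log2, at 15 min with total-count scaling), and the medians were -0.03 and 0.09; with vvd, at 0 counts at 15 min, set at its bound the first was 0.01. The second became -0.23 with total-count scaling. wc-1 was lower past 2-fold at 15 min with total-count scaling (-1.62) and in the authors' FPKM (-1.29). Some genes were higher in the mutant as in the wild type: the clock-controlled gene ccg-1 (NCU03753) was 4.36- and 9.67-fold higher (wild type 5.63 and 11.8), bli-3 3.71- and 3.89-fold, and cat-1 5.48- and 4.49-fold.

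Smaller differences in the mutant were those of al-2 (2.48-fold higher) and csp-1 (2.32-fold higher) at 15 min, both below 2-fold with total-count scaling (0.53 and 0.44, log2), and of con-10 at 45 min (2.96-fold higher). Transcription factors had 1 of 7 members higher at 15 min and 0 at 45 min, with medians of 0.30 and 0.00; the first was -0.47 with total-count scaling. In the authors' FPKM sub-1 (NCU01154) was higher in the mutant past 2-fold (2.10 and 1.42, log2, against 0.21 and 0.33 from counts) and in the wild type at 15 min (2.16 against 0.74). ccg-14 (NCU07787) was 3.34- and 3.16-fold lower. Of the conidiation list, 2 of 11 members were higher and 1 lower at 15 min, and 4 higher and 1 lower at 45 min, with medians of 0.29 and 0.36; the first was -0.48 with total-count scaling. The counts became 2 higher and 2 lower, and 3 and 2, with total-count scaling, where bli-4 (-1.23 at 15 min) and con-8 (-1.30 at 45 min) were lower. con-6 at 45 min was short of 2-fold there (0.73) and in the authors' FPKM (0.97), while with DESeq2 size factors 3 were higher at 15 min. Among melanin genes 2 of 4 were lower at 15 min and 3 of 4 at 45 min, with medians of -0.82 and -1.13; per-1 was 2.24- and 3.80-fold lower, but in the authors' FPKM its log2 values were 0.40 at 15 min, of the opposite sign, and -0.61 at 45 min. With total-count scaling 4 of 4 melanin genes were lower at 15 min, and in the authors' FPKM 1 of 4 was lower at each time, with tetrahydroxynaphthalene reductase-1 at -0.97 at 45 min. fmf-1 (NCU09387) was 6.97- and 2.82-fold higher, and its log2 folds were 0.37 and 0.45 once the assembly components of the 4 most abundant features were removed. No heat shock or housekeeping gene passed the rule with TMM. With total-count scaling hsp70-1, hsp80, hsp60, grp-78, gpd-1 and eno were lower at 15 min (-1.04 to -1.41, log2) and hsp80 and hsp60 at 45 min (-1.14 and -1.13), and in the authors' FPKM hsp80 just passed 2-fold at 15 min.

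Genes passing the rule in the mutant numbered 425 higher and 243 lower at 15 min, and 200 and 188 at 45 min. Simulated unchanged pairs gave 310 and 330, and 301 and 317, or 147 and 174, and 141 and 155, with the spread of the mutant lit pair. NCU09049 had 2955 counts at 15 min against 191 in the dark, NCU03506 had 1001 at 45 min against 90, and NCU05768 had 196 at 45 min against 19866. Genes higher at both times numbered 144, against 10.9 for independent sets, 89.8 with the spread of all libraries and 33.7 with that of the mutant lit pair. Genes lower at both times numbered 86, against 5.85, 51.2 and 18.0. The mutant 15 min library held 42.7% of its counts in 24 features of those abundant components, against 7.72% in the mutant dark library. Its calls also differed between scalings, and the cause of this was not tested. Higher genes were 63.6% of its calls with TMM, 5.34% with total counts (143 higher, 2535 lower, median of all genes -0.81) and 31.4% in the authors' FPKM (median -0.34), and at 45 min 51.5%, 20.5% and 48.3%.

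In the edgeR test of light in the mutant, 0 genes rose and 4 fell, with 308 genes at an unadjusted p under 0.05. The DESeq2 Wald test called 65 higher and 22 lower, and limma-voom 0 and 5. The 4 genes were NCU17268 (fell by 5.19, SE 0.388, adjusted p = 0.0225), NCU05763 (fell by 4.55), NCU05762 (fell by 4.86) and NCU05766 (fell by 3.98), the last pair named after its values were seen. Adjusted over the list alone, 3 of 11 conidiation genes changed: ccg-1 (2.81, adjusted p = 0.0307), bli-3 (1.93, 0.0285) and ccg-14 (-1.70, 0.0197). So did cat-1 (2.32, 0.0129) and 2 of 4 melanin genes, per-1 (-1.52) and tetrahydroxynaphthalene reductase-1 (-1.30), at 0.0407 each. The melanin count was 0 with DESeq2 size factors or a count minimum of 100. None of these 6 passed over all genes. Without the mutant 15 or 45 min library, no gene of these 3 lists and no gene over all passed (150 and 274 unadjusted); without the wild-type 15 or 45 min library, 12 and 14 genes rose and 11 and 12 fell. These fits too take their spread from the lit pair of 1 strain.

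Set side by side, the light responses of the strains were related across genes, with r = 0.471 at 15 min and 0.228 at 45 min (Spearman 0.352 and 0.115), where genes are not independent replicates. At 15 min 275 genes were higher in both strains, against 42.2 for independent sets, and 66 were lower in both, against 13.3. At 45 min these were 111 (19.7) and 59 (19.4). Of the 52 genes over 16-fold higher in the wild type at 15 min, 28 were higher in the mutant too, and 26 of these were on no fixed list; at 45 min 18 of 52 were higher in the mutant too. The 140 genes that rose in the wild-type test had a median log2 fold of 3.22 there and 0.25 in the mutant, with the same sign in 95. The 57 that fell had medians of -2.60 and -0.49. Both sets were chosen on the wild-type test, which favours larger differences there than in the mutant. Total-count scaling moved the median of all genes in the mutant to -0.81 at 15 min and -0.34 at 45 min. A mutant median as small as 0.25 may therefore change sign with scaling. With total-count scaling the 275 shared genes became 122.

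**Figure D2:**
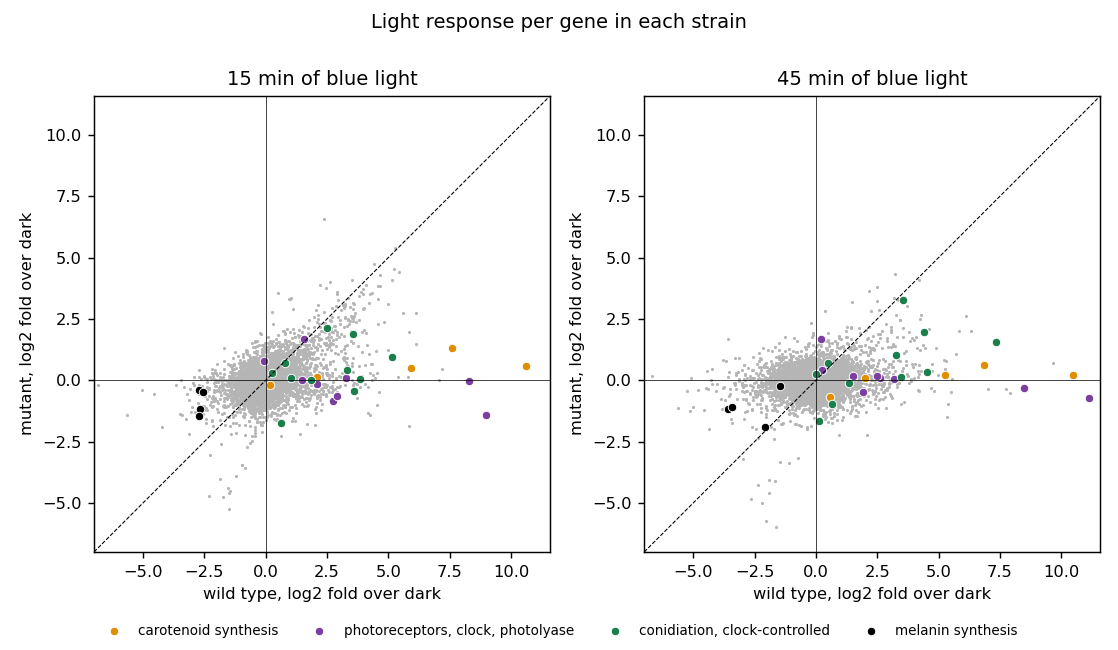
Log2 fold over dark in the mutant against that in the wild type at 15 and 45 min for 7810 genes (grey), with 4 gene lists in colour and a dashed line of equal response, 1 library per group. At 15 min carotenoid genes have medians of 5.92 on the wild-type axis and 0.50 on the mutant axis (-0.27 with total-count scaling), with ylo-1 (NCU04013) at 0.17 on the former and al-2 at 1.30 on the latter.

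The interaction tests whether light responses differed between strains. al-1 differed by 10.20 (log2, SE 0.682, adjusted p = 0.0112), cry by 8.65 (SE 0.59, 0.0112) and NCU00999 by 7.38 (SE 0.558, 0.0145), each with the larger response in the wild type. Adjusted over the list alone, 7 of 9 photoreceptor, clock and photolyase genes differed, among them vvd (12.60), phr (3.31) and wc-1 (3.03), and 4 of 5 carotenoid genes (al-2 6.30, al-3 5.27). So did 6 of 11 conidiation genes (con-10 5.35, bli-4 3.66; with its top feature alone bli-4 was 1.62 and 1.12 in the mutant, against -0.46 and 0.14 from summed counts, and over 16-fold higher in the wild type), 1 of 7 transcription factors (fl 3.10) and 2 of 4 melanin genes, the tetrahydroxynaphthalene reductases (-1.79 and -2.16). The last 2 lists had 0 genes with limma-voom; 0 transcription factors also passed with a count minimum of 100, and 0 melanin genes with the top feature per gene. Over all genes edgeR called 3 higher and 0 lower (595 unadjusted), the DESeq2 Wald test 144 and 31, and limma-voom 2 and 0. Over the lists alone, no count fell without the wild-type 15 or 45 min library. The conidiation and oxidative stress counts rose without either of them. Without the mutant 15 or 45 min library no gene passed over all genes (403 and 402 unadjusted), and over the lists alone 6 photoreceptor, 4 carotenoid, 4 conidiation, 0 transcription factor and 0 melanin genes did. Without the wild-type 15 or 45 min library 150 and 85 genes were higher and 72 and 13 lower, again with the spread of the lit pair of 1 strain.

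Mutant and wild type were next compared in the dark, before any light. Melanin synthesis genes stood out: all 4 of 4 were lower in the mutant, per-1 23.6-fold (95% interval 21.4 to 26.1), tetrahydroxynaphthalene reductase-1 12.4-fold, scytalone dehydratase (NCU07823) 12.0-fold and tetrahydroxynaphthalene reductase-2 (NCU09390) 8.23-fold. Their median was -3.59. The conidiation gene con-6 was 2.50-fold higher in the mutant, cat-1 was 2.35-fold higher (just short of 2-fold in the authors' FPKM) and mat A-1 2.15-fold lower, the last short of 2-fold with total-count scaling (-0.98, log2). Carotenoid genes did not pass the rule (median -0.01, or 0.11 with total-count scaling; al-1 was -1.06 in the authors' FPKM with a pseudocount of 0.1), and vvd had 5 counts in the mutant and 16 in the wild type (4.59-fold lower, with a lower 95% bound of 1.61). That difference was short of 2-fold with a prior count of 10 (-0.93, log2) and in the authors' FPKM (-0.41 and -0.77 with pseudocounts of 1 and 0.1).

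**Figure D3:**
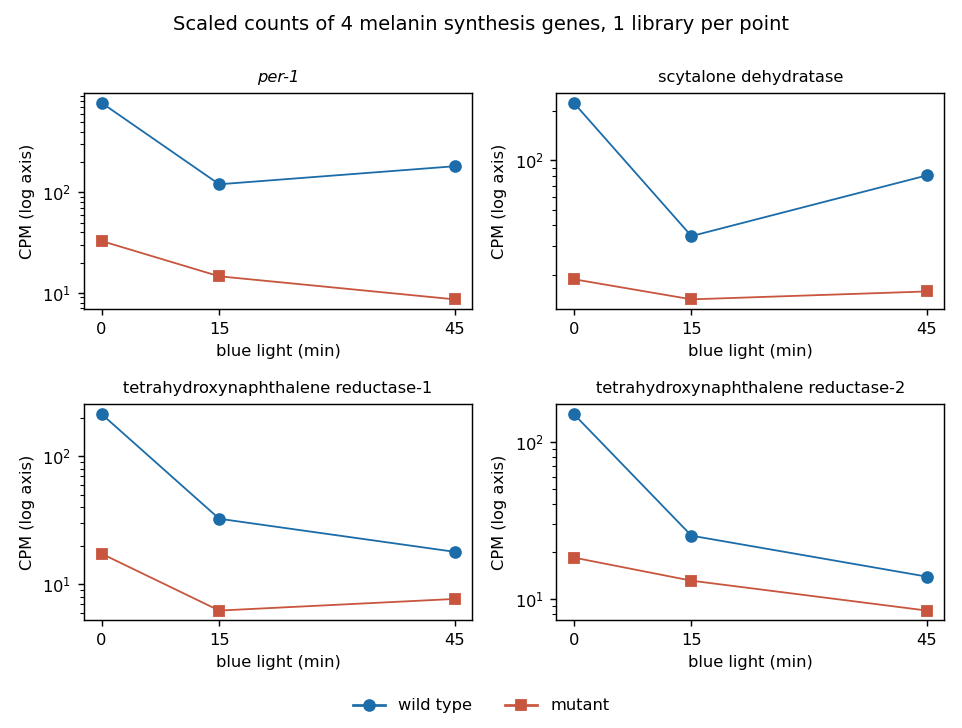
CPM (scaled counts, log axis) of the 4 melanin synthesis genes against minutes of blue light, wild type as blue circles and mutant as red squares, 1 library per point. In the dark the mutant lies 8.23- to 23.6-fold below the wild type, and the wild type is lower in light than in the dark.

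Transcription factors, heat shock proteins and housekeeping genes had no member past the rule in the dark. As a list, though, the transcription factors were higher in the mutant by a median of 0.44 (log2), at percentile 99.9 of the matched random lists. Over all genes 140 were higher and 212 lower in the mutant, fewer than in simulated unchanged pairs (311 and 304). The spread of those pairs comes from lit libraries that differ in light time, so it may exceed that of unchanged libraries. The simulated counts therefore cannot tell whether the dark libraries differ beyond the spread of unchanged ones. The 2 dark libraries correlated at r = 0.963. NCU05005 had 2123 counts in the mutant and 36 in the wild type, and NCU16961 had 23 and 8540. Higher genes were 39.8% of the calls, 52.0% with total-count scaling (median of all genes 0.14) and 50.9% in the authors' FPKM (0.11).

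After light, the mutant was lower than the wild type for most light-associated genes; these comparisons use the same lit wild-type libraries as above and add no independent evidence. vvd had 0 counts in the mutant at 15 min against 10331, at least 1281-fold lower by the exact 95% interval (1575 with the floor of 3 counts), and 1 against 39031 at 45 min, a ratio of 31304 (5618 to 1236480). al-1 was 1475- and 1748-fold lower, cry 357- and 513-fold, al-2 72.7- and 69.8-fold, con-10 9.71- and 29.4-fold and frq 15.2- and 9.57-fold. Medians at 15 and 45 min were -5.61 and -5.22 for carotenoid genes, -3.06 and -2.64 for the photoreceptor list, and -1.38 and -1.64 for conidiation genes. phy-1 (NCU04834, a phytochrome) was 3.30- and 2.10-fold higher in the mutant, adv-1 4.04- and 2.17-fold higher, and cat-3 2.21- and 4.48-fold higher. The ratios of phy-1 were short of 2-fold in the authors' FPKM (0.95 and 0.88, log2), and that of cat-3 at 15 min with total-count scaling (0.85).

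Melanin genes stayed lower in the mutant in light, 3 of 4 at each time, with medians of -1.81 and -1.77; per-1 was 8.22- and 21.0-fold lower. In the authors' FPKM 4 of 4 were lower at 15 min and 2 of 4 at 45 min, where tetrahydroxynaphthalene reductase-1 was -0.83. Mating and fruiting body genes had medians of 0.57 and 0.44, the first of which was -0.02 in unfiltered FPKM. At 45 min sod-2 (2.52-fold) and eno (2.47-fold) were higher and the chaperone genes hsp60 (2.85-fold) and hsp80 (2.09-fold) lower; no heat shock gene passed at 15 min. Over all genes, 473 were higher and 634 lower at 15 min, and 770 and 810 at 45 min (simulated 311 and 329, and 313 and 317). NCU07231 had 5093 counts in the mutant at 45 min and 180 in the wild type. Higher genes were 42.7% of the calls at 15 min, 19.6% with total-count scaling (median -0.28) and 20.2% in the authors' FPKM (-0.30); at 45 min they were 48.7%, 45.1% and 36.9% (-0.13 in FPKM).

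The strain test pooled the 3 light conditions. Melanin genes were lower in the mutant in 3 of 3 conditions by the median, and 4 of 4 fell when adjusted over the list alone: per-1 (-4.02, SE 0.394, adjusted p = 0.000549), scytalone dehydratase (-2.44) and tetrahydroxynaphthalene reductase-1 (-2.46), both at 0.00601, and tetrahydroxynaphthalene reductase-2 (-1.62, 0.0272). Of the photoreceptor list 4 of 9 changed: wc-1 (-2.80), vvd (-11.13) and frq (-2.69), at 0.0338 each, and phy-1 (1.23, 0.025). Over all genes edgeR called 0 in either direction, with 1043 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0623, for NCU01903 and NCU05005. The DESeq2 Wald test called 140 higher and 235 lower, and limma-voom 1 and 3. When 1 library is left out, the light block fits its partner exactly. Each such fit rests on the remaining pairs with 1 residual degree of freedom, so leaving out either library of a pair is not a separate check. Over the lists alone, more carotenoid, transcription factor, conidiation, mating and oxidative stress genes passed without either dark library than in the main fit. Without the wild-type dark library edgeR called 441 higher and 587 lower, and without the mutant dark library 437 and 587; without any one of the other 4 libraries it called 0 (258 to 507 unadjusted). Over the lists alone, 0 photoreceptor genes passed without any one of the 4 lit libraries and 8 without either dark library, while 3 or 4 melanin genes passed in each of these fits.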

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

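Of the tests in this part, those on carry-over of wild-type RNA, on the wild-type dark library and on the mutant dark library were chosen after the results were seen.

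Light responses differed between the strains by the interaction test for al-1 (10.20, log2), cry (8.65) and NCU00999 (7.38), each larger in the wild type. Over the lists alone the same test singled out 7 photoreceptor, clock and photolyase genes, 4 carotenoid genes, 1 transcription factor gene, 6 conidiation genes and 2 melanin genes. Mating and fruiting body genes went opposite ways by the median, at -0.44 and -0.29 in the wild type and 0.19 and 0.20 in the mutant (15 and 45 min); this difference was not tested as a list, and the mutant medians were -0.59 and -0.11 with total-count scaling and -0.29 and -0.09 in the authors' FPKM. The features without an ID, which no comparison used, held 32, 32 and 30 counts in the wild type (dark, 15 and 45 min). In the mutant they held 59, 25 and 32. These are sums over 26 features and at most 0.000578% of a library's counts. They exceed the floor of 3 counts, but that floor is for 1 gene and is no measure of such sums.

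At 15 min 275 genes were higher in both strains, against 42.2 for independent sets. Carry-over of lit wild-type RNA into the mutant 15 min library is argued against by al-1, cry and vvd, whose highest level there was 0.28% of the wild type's, where the 275 genes had a median of 98.2%. A larger share of abundant RNA stays open: the 275 genes were lower by a median of -1.01 in the mutant at 45 min than in the wild type at 15 min, libraries whose levels of the abundant gene NCU00400 differed by -0.14, but choosing genes on the wild-type 15 min library itself lowers that median. Scaling shifts all genes of a library alike, so it sets how many pass a fixed 2-fold threshold. The count fell to 122 with total counts, so the number of shared genes depends on scaling. By the rule set beforehand, a fall of over 1.5 times pointed to scaling. Sharing beyond independent sets remained there, with 122 genes against 9.98, a comparison outside that rule. A shift of all genes alike leaves their order within each strain in place. Such a shift could hardly remove the excess, so the comparison does not decide whether scaling is its source. A response to light that does not need an intact Sfwc-1, or to handling at the time of treatment, may be present and was not tested, since no mycelium was handled without light.

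Melanin synthesis genes were lower in the mutant in the dark, with a median of -3.59. An unusual wild-type dark library as the whole cause is argued against by the 15 and 45 min comparisons, which do not use it and whose medians were -1.81 and -1.77. Scaling is argued against as well, since the highest median under the other scalings was -3.37. A strain difference that is present in the dark and smaller in light is a hypothesis left by these tests, with 1 library per group. In the interaction test 2 of 4 genes passed over the list alone, and 0 with limma-voom. At 45 min per-1 hardly followed this pattern, unlike the other members. It had 775 CPM in the wild type and 32.8 in the mutant in the dark, and 181 and 8.62 CPM at 45 min. Over all genes the edgeR strain test called 0 of 7810 genes (1043 unadjusted; 140 higher and 235 lower with the DESeq2 Wald test, 1 and 3 with limma-voom), though 4 of 4 melanin genes passed over the list alone.

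A run of 7 genes with IDs from NCU05761 to NCU05768 was lower with light in the mutant, with medians of -4.38 at 15 min and -4.59 at 45 min, against -1.50 and -2.02 in the wild type. The mutant dark library alone is a candidate source of the larger mutant response for part of the run. In the dark 6 of the 7 genes were higher in the mutant than in the wild type (run median 2.70, and NCU05768 had 1555 CPM against 187). NCU05761 was not (283 against 414 CPM), though it too was lower with light in the mutant. In light the medians of mutant over wild type were -0.13 and 0.56, with members from -1.52 to 4.08 at 45 min. Whether that library reflects the strain or a single culture cannot be settled with 1 library.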

How the results depend on the processing

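Fits without a library, and removal of the abundant assembly components, were chosen after the data were seen. Of 308 counts and correlations recomputed under other settings, 232 stayed within 1.5 times of the main count or within 0.1 of the main correlation; with a library or pair left out this held for 20 of 46. Of 476 ratios of list genes, 77 changed their call under at least 1 of 13 settings, and 20 of 63 list medians changed sign, among them mutant medians near 0. In the wild type the medians of the carotenoid, photoreceptor, conidiation and melanin lists kept their sign under each setting. Except where stated, the cause of a difference was not tested.

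Total-count scaling, which leaves the abundant RNAs' share in place, gave 953 genes lower in the wild type at 15 min (426 with TMM), 143 higher and 2535 lower in the mutant at 15 min (425 and 243), and 120 and 465 at 45 min (200 and 188). It gave 230 genes higher in the mutant than in the wild type at 15 min (473) and 122 higher at 15 min in both strains (275). Its tests called 277 and 230 genes (higher and lower) for light in the wild type (main 140 and 57), 26 and 54 in the mutant (0 and 4), 165 and 14 for the interaction (3 and 0), and 10 and 18 between strains (0 and 0).

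A minimum mean of 100 counts, which tests fewer genes, gave 274 genes lower in the wild type at 15 min, and 125 and 106 lower in the mutant at 15 and 45 min. Assembled features not summed per gene, of which there are more, gave 1555 higher and 1040 lower in the wild type at 15 min, 1565 and 1576 at 45 min, 928 and 811 in the mutant at 15 min, and 630 and 538 at 45 min. Between strains this gave 481 and 581 in the dark, 987 and 1407 at 15 min, and 1550 and 1654 at 45 min; r across strains at 15 min was 0.354 (0.471), and 551 and 271 features were higher in both strains at 15 and 45 min (275 and 111). Its tests called 24 lower features in the wild type (57), 0 in the mutant (4; 524 unadjusted), and 1 lower between strains (0).

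The authors' FPKM with a pseudocount of 1 gave 695 and 313 genes lower in the mutant at 15 and 45 min, 265 higher in the mutant than in the wild type in the dark (140), and 290 higher and 1149 lower at 15 min (473 and 634). Counts from FPKM rest on the 2-fold ratio alone, while the main counts also need an interval that excludes 1. How much of the differences comes from this looser rule was not tested. With a pseudocount of 0.1 there were 851 lower in the mutant at 15 min, 330 higher and 387 lower at 45 min, 312 higher between strains in the dark and 1270 lower at 15 min, and r at 15 min was 0.367. Without a filter there were 1273 higher in the wild type at 45 min (768), 925 lower in the mutant at 15 min, 481 and 464 at 45 min, 402 and 430 between strains in the dark, and 1416 and 1322 lower at 15 and 45 min; r was 0.294 and 0.128 (0.471 and 0.228), and 174 genes were higher in both strains at 45 min. per-1 in the mutant at 15 min reversed from -1.15 to 0.40, 0.41 and 0.40 under these FPKM settings, and the mating list between strains at 15 min went from 0.57 to -0.018 in unfiltered FPKM.

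The DESeq2 Wald test called 403 and 164 genes for light in the wild type, 65 and 22 in the mutant, 144 and 31 for the interaction and 140 and 235 between strains. It called each of the 197 genes of the wild-type edgeR test, and limma-voom called 186 of them. limma-voom called 1 and 3 genes between strains. Without a count minimum edgeR called 1 and 7 genes in the mutant, 12 higher for the interaction, and 1 and 1 between strains; with the top feature per gene it called 5 higher for the interaction.

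With a library or pair left out, edgeR called 0 to 368 genes higher and 0 to 262 lower for light in the wild type, 0 to 14 and 0 to 12 in the mutant, 0 to 150 and 0 to 72 for the interaction, and 0 to 441 and 0 to 605 between strains. Without a lit library the light and interaction tests have 1 residual degree of freedom and the spread of 1 strain's lit pair. The strain test has 1 residual degree of freedom without any library or pair, and its fits without either library of a pair are not separate checks. The counts of 0 came from leaving out a lit mutant library for the light tests and a lit library or pair for the strain test, except 0 higher in the mutant without the wild-type dark library; unadjusted counts in these fits ran from 150 to 922. The larger counts came from leaving out a lit wild-type library, or a dark library or pair for the strain test. Over the lists alone, carotenoid and melanin genes kept counts of 4 and 4 for light in the wild type in each such fit.

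Depth limits the genes near the floor: vvd had 16 and 5 counts in the dark libraries and 0 and 1 in the lit mutant, so its ratios have wide intervals. Of 76 list members 8 were below the count minimum.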

Other observations

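The count of neighbouring IDs among genes lower in the mutant, and the test on features seen in 1 strain, were chosen after the results were seen; the others were set before their results were seen.

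The 275 genes higher at 15 min in both strains differed between the strains at that time by a median of -0.03 (log2, quartiles -0.52 and 0.40), and 65 of them by at least 2-fold. The median was -0.31 with total-count scaling and -0.28 in the authors' FPKM. Their median log2 folds over dark were 2.21 at 15 min and 1.26 at 45 min in the wild type, and 1.71 and 0.82 in the mutant. At 45 min 229 of them were below their 15 min level in the wild type and 244 in the mutant, and 166 and 120 still passed the size rule. A further 500 genes passed the rule at 15 min in the wild type and not in the mutant, with wild-type medians of 1.55 and 1.48 and mutant medians of 0.13 and 0.03. Of these, 311 were below their 15 min level in the wild type at 45 min and 334 still passed. Choosing genes on their 15 min value favours a lower value at 45 min in both classes, and the difference between the classes was not tested.

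In the wild type, genes with consecutive Neurospora locus numbers were called together more often than in random sets of as many genes (100000 sets, one-sided permutation tests). The random sets were drawn from all kept genes without matching for expression. Their p-values treat genes as exchangeable and cover no spread between libraries, and both times share 1 dark library. Genes higher at both times held 75 such pairs (random mean 23.8) and genes lower at both times 30 (7.52; 3 of the 30 lie in the run from NCU05761 to NCU05768), each with a permutation p = 1e-05, the smallest these sets can give, and an adjusted p of 1.5e-05. Genes higher at both times in the mutant held 6 pairs (1.96, permutation p = 0.013, adjusted p = 0.013). Genes lower at both times in the mutant held 9 pairs (0.700), but 5 of them lie in that run, which prompted the count, so it is given without a p and supports nothing further. Clusters of neighbouring genes that change together are a hypothesis from the first 3 counts. Fragments that share sequence between neighbouring IDs may add to them: 2, 1 and 0 pairs had their top features in 1 assembly component each. Other features of these IDs were not compared, and other sharing of reads was not tested. Gene order in Sordaria is not in the data.

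Some features had at least 10 counts in each library of 1 strain and 0 in the other strain's: 13 in the wild type alone and 5 in the mutant alone, 18 in all. Of the 10 splits of the 6 libraries into equal sets, 1 (the real one) gave as many, and the highest of the others gave 7, but 10 splits are too few for a share under 0.05. Of whole genes, NCU08733 had 140, 387 and 243 counts in the wild type and NCU09152 96, 252 and 181, with 0 in each mutant library, at least 226- and 155-fold lower with a floor of 3 counts for the 3 mutant libraries together, not 3 for each. The genes were named after their values were seen. Sequence variants between the strains could place the reads of 1 gene on different features, which the value of 18 does not separate from a difference in expression.

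The edgeR strain test called 0 genes (1043 unadjusted; 140 and 235 with the DESeq2 Wald test, 1 and 3 with limma-voom). A count of 0 is reached by any split, so the 10 of 10 splits with as many genes say nothing about it; the highest of the others also called 0, and 10 splits are too few for a share under 0.05. Opposite calls in the strains at both times were made for 4 genes.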
